A study of Homo sapiens with 16 samples.

How the data were processed

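Gene expression was measured on Affymetrix HG-U95Av2 chips, which carry 12625 probe sets, 67 of them control probe sets. Per the labels, total RNA of 3 infections was pooled, converted to cDNA and labelled with biotin, each pool was hybridized 2 times, and each chip was scanned before and after an antibody enhancement step. The same labels place every scan in a vector group, an experiment, a hybridization and a scan. All 16 columns of the deposited table matched a sample by its label, and 0 columns were left unmapped.

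The values the authors deposited are linear intensities, 1 per probe set and scan. Their mean after trimming 2% at each end was near 500 in every scan, which shows a scaling of each array to a common target before deposit. The program that summarised the probes and set this scale is not given in the sources used here. No value was at or below 0, so the planned floor was the lowest deposited value and changed nothing. Affymetrix scans give no count, and a low intensity cannot be told from background.

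From these deposited intensities, log2 values were computed, and the 16 scans were quantile normalized. The 2 scans of a chip were averaged, then the 2 hybridizations of a pool, which left 4 pool means. Probe sets with a mean log2 level under the 40th percentile (6.30, an intensity of 78.8) were left out, as were control probe sets, which left 7535. Mean intensities in the text are averages of deposited values over each pool, and log2 differences come from the normalized values. Where the mean of a vector or of an experiment lay below the filter level, and for both FHIT probe sets, the fold is a lower bound. It is computed from normalized log2 values, with the dim side averaged over, per scan, the higher of the filter level and its own value.

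Differences were tested with lmFit and eBayes (intensity trend) of limma 3.58.1 in R 4.3.3, with vector and experiment as terms, which leaves 1 residual degree of freedom per probe set. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The experiment is a shared thaw of cells per the labels, so pools of the same experiment are paired. As a check of the pairing, the deviations of the AdFHIT and AdLACZ pools from their vector means correlated at 0.80 across probe sets. The experiment term was read from the same fit, and the vector by experiment term from a fit to the 8 hybridizations. With the experiment as a term, p-values of the vector term set its mean difference against a spread. That spread joins the disagreement between the 2 experiments, with 1 residual degree of freedom, to a spread shared across probe sets. The shared part, with 7.36 prior degrees of freedom, carries most of the weight. Each pool is a mixture of 3 infections.

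Gene names come from the platform annotation, updated through Entrez identifiers. Of the probe sets, 10961 have 1 symbol, 545 have several and are not named, and 1119 are not listed there and are unnamed here. Of the symbols, 10949 matched a current table and 12 were kept as listed. No genome build applies to the chip, so no coordinates are given. The chip's probe sets of a gene can disagree, and where a gene named by the rule below had others tested, their vector differences are given.

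Before the data were examined, 31 gene lists were fixed for pathways tied to FHIT, to adenoviral transduction and to lung carcinoma, with markers of other cells and reference genes. Lists were tested with camera (preset correlation 0.01) on 1 probe set per gene, that with the highest mean level, over 5457 genes. A list needed 5 tested genes, which 28 lists had. The estimated correlation and fry were run beside it. To place a list within 1 experiment, its median was set among 10000 random lists of the same size and matched level. Members were also adjusted over the list alone.

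The rule for named genes was fixed in advance. It took every FHIT probe set, then up to 10 genes per direction past the threshold with the same sign in all 8 matched pairs of scans, filled to 10 in order of p where fewer passed. It added the 4 members with the smallest p of each list past the threshold, and 3 members each of the p53, apoptosis, beta-catenin and AKT lists. Genes named for the difference between experiments or for the vector by experiment term were chosen after their values were seen.

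The fits were tested on simulated data. In 20 simulations of 4 pool means over 7535 probe sets, each with 200 changed and spreads drawn from the fitted prior distribution, the test called 35.4% of changes of 1.5-fold, 69.3% of 2-fold and 93.7% of 4-fold. Of all its calls 14.3% were unchanged probe sets, above the 5% aimed at. An earlier version of the simulation, with spreads taken from the moderated variances, called more of the changes and was replaced. For gene lists over 5457 genes, camera called 1 of 560 unchanged list tests, and a p53 list shifted by 0.3 in 20 of 20 simulations, but in 0 of 20 with an estimated correlation. Genes were simulated as independent, so these counts do not cover false calls of lists whose genes vary together. On the 8 hybridizations, fitted without the vector by experiment term, the estimated correlation was 0.56 for the G2/M and mitosis list and 0.36 for the E2F list. With that term in the fit it was 0.039 and 0.028.

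Alternatives covered the scans, the hybridizations, the pools, the experiment term, normalization, filter, floor, pseudocount of 32, eBayes options, thresholds and list tests. A chip with low spike-in values was left out as an alternative added after seeing the data, as were an estimated correlation on the 8 hybridizations and the alternatives for the agreement of the experiments, the vector by experiment term, the scan slope and the ACTB difference. Figures were drawn with matplotlib 3.10.9.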

Results

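Expression was profiled in NCI-H460, a human large cell lung carcinoma line described in the labels as negative for FHIT, a tumour suppressor of the histidine triad family. Cells received an adenovirus carrying human FHIT (AdFHIT) or a control adenovirus (AdLACZ) at an MOI of 10, and RNA was taken after 48 h. RNA from 3 infections was pooled per vector, and everything was run in 2 experiments, each from a new thaw of cells. Every one of the 4 RNA pools was hybridized to 2 oligonucleotide chips, and each of the 8 chips was read in 2 scans, before and after an antibody step that amplifies the signal, which gave 16 scans. The replicate is therefore the experiment, with n = 2 per vector. Deposited intensities had a trimmed mean between 500.25 and 500.29 in every scan and medians between 126 and 171. The number of arrays limits the precision of every value below.

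The first comparison asked whether the transgene was present where the labels put it. FHIT was measured by 2 probe sets, and both were far higher in the AdFHIT pools in both experiments. The brighter probe set read 41187 ± 3176 intensity units with AdFHIT and 44.4 ± 5.63 with AdLACZ (SD, n = 2). The other read 30532 ± 5337 with AdFHIT and 85.4 ± 35.9 with AdLACZ (SD, n = 2). The fitted log2 differences were 10.09 (SE 0.11, limma adjusted p = 5.65e-10) and 8.47 (SE 0.11, adjusted p = 1.42e-09). The AdLACZ scans placed the gene between percentiles 12.8 and 46.4 of their own values, and the AdFHIT scans placed it between percentiles 99.66 and 99.95. Set against the intensity of 78.8 that served as the filter on dim probe sets, or the control's own value in a scan where higher, FHIT was at least 479-fold higher by the brighter probe set and at least 330-fold higher by the other.

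**Figure D1:**
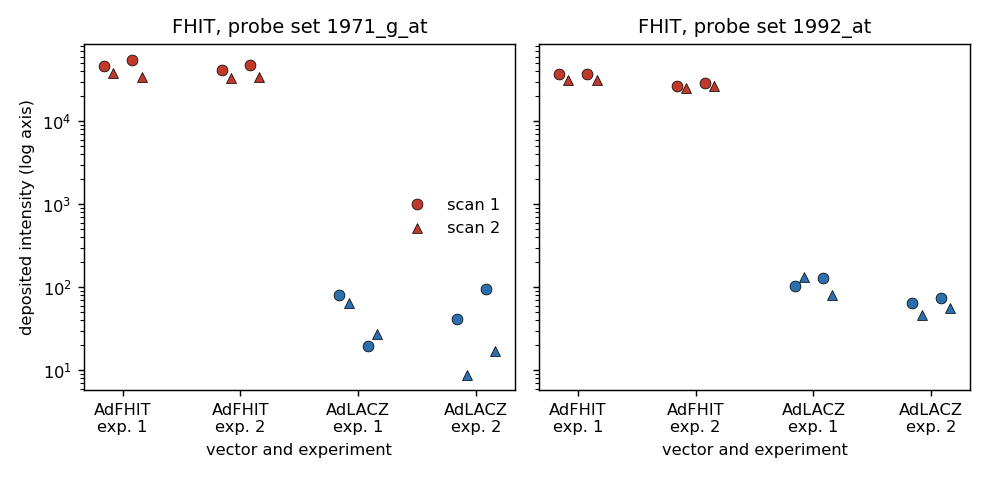
Deposited intensity of the 2 FHIT probe sets on a log axis in each of the 16 scans, grouped by vector and experiment; circles are scans before and triangles scans after the antibody step. AdFHIT scans lie between 24934 and 55151, and AdLACZ scans between 8.89 and 131.5.

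The main comparison asked which transcripts differed between FHIT-transduced and control cells. Beyond FHIT itself, almost no single transcript passed the test, so the expression of named genes is given here mostly as values. Of 7535 probe sets tested, 3 passed an adjusted p of 0.05 in limma: the 2 FHIT probe sets, which rose, and a probe set unnamed here, which fell. The latter is not paired with a gene in the annotation used and was singled out after its values were seen. It read 217 ± 149 with AdFHIT and 698 ± 396 with AdLACZ (SD, n = 2), a log2 difference of -1.77 (SE 0.18, adjusted p = 0.0160), with -2.01 in experiment 1 and -1.53 in experiment 2. At an unadjusted p under 0.05 there were 468 probe sets, where 376.75 are expected by chance. With the 8 hybridizations fitted and the RNA pool as a random block, 21 probe sets passed, and with hybridization 1 of every pool alone, 15 passed. With the 8 hybridizations taken as independent, 4 passed. The random block fit treated hybridizations of a pool as less alike than independent ones (consensus correlation -0.27), so its 21 calls carry little weight. The unnamed probe set passed in 13 of 21 settings and lost its call without the experiment as a block, where 2 probe sets passed, both of FHIT.

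Several genes read lower with AdFHIT in all 8 matched pairs of scans without passing that threshold. The pairs come from 2 experiments, so they are not 8 independent comparisons. The rule picked genes for this pattern, so the pattern itself adds no support. BCAP31, a membrane protein of the endoplasmic reticulum, differed by -0.48 on the log2 scale (SE 0.07, limma adjusted p = 0.199). CBX3, a heterochromatin protein, differed by -0.59 (SE 0.09), and the chemokine CXCL5 by -0.74 (SE 0.12), both at an adjusted p of 0.203. The tRNA exporter XPOT (-0.54), the DNA polymerase epsilon subunit POLE3 (-0.63), ATP9A (-0.69) and SPOCK1 (-0.45) followed. SAT1, which acetylates polyamines, differed by -0.33 with 1 AdLACZ chip apart from the other 3, the mitotic kinesin KIF11 by -0.94 and the ribosomal protein gene RPL34 by -0.46. Adjusted p-values of these 7 genes lay between 0.413 and 0.685. In experiments 1 and 2, POLE3 read -0.87 and -0.39, KIF11 -1.40 and -0.48, and RPL34 -0.70 and -0.21.

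On the other side, CDKN1A, the cyclin-dependent kinase inhibitor induced by p53, read 3984 ± 1404 with AdFHIT and 2933 ± 1184 with AdLACZ (SD, n = 2). Its log2 difference was 0.43 (SE 0.08, adjusted p = 0.413), with 0.48 in experiment 1 and 0.39 in experiment 2. WNT6 (0.31), the small GTPase RHOQ (0.48), SNCG (0.57) and NINJ1 (0.69) were also higher in all 8 matched pairs. The same held for the nuclear receptor NR4A1 (0.76), the GABA transporter SLC6A11 (0.98) and the neurotrophic ligand NRTN, which read 1.54 in experiment 1 and 0.45 in experiment 2, and for ROM1, at least 1.55-fold higher over a control level below the filter. Adjusted p-values of these 8 genes lay between 0.621 and 0.714. In experiments 1 and 2, NR4A1 read 1.22 and 0.31, and NINJ1 0.97 and 0.40. SLC6A11 lay below the filter level in the AdLACZ pool of experiment 1, so the size of its difference is not exact. Other tested probe sets of RHOQ (-0.02), CBX3 (-0.11) and SAT1 (-0.05) showed little difference, and those of NR4A1 read -0.23 and 0.65.

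Gene lists fixed before the data were examined showed where small differences ran the same way. Of 28 lists tested with camera, 5 passed an adjusted p of 0.05, 3 of them lower and 2 higher with AdFHIT. The G2/M and mitosis list was lower, with a median log2 difference of -0.37 over 30 genes (camera adjusted p = 2.62e-14; adjusted p = 0.885 with an estimated correlation between genes). The list of E2F targets and DNA replication genes was lower as well, with a median of -0.36 over 31 genes (camera adjusted p = 2.57e-10; adjusted p = 0.885 with an estimated correlation). None of the 5 calls holds with an estimated correlation. On the pool means that test called a simulated list shift of 0.3 in 0 of 20 simulations, so a miss does not show that a list is unchanged. With the AdFHIT pool of experiment 1 left out and no block, the mitotic and replication lists read higher. With the AdLACZ pool of experiment 2 left out they read lower, and the calls were lost in both cases. Leaving out a pool with no block adds the difference between experiments to that between vectors, so these fits do not test the vectors alone.

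Among mitotic genes, TOP2A, the topoisomerase that untangles chromosomes before division, read 745 ± 676 with AdFHIT and 1260 ± 445 with AdLACZ (SD, n = 2), a log2 difference of -1.10 (SE 0.29, limma adjusted p = 0.701). KIF11 (-0.94), the centromere protein CENPF (-0.60) and HMMR (-0.55) came next. In the replication list, the origin licensing factor CDC6 (-0.92), CDC45 (-0.87) and MCM2 (-0.40) of the replicative helicase and the histone chaperone subunit CHAF1A (-0.37) had the smallest p-values. Other tested probe sets of TOP2A read -0.79 and -0.66, and that of CDC6 read -0.41. In experiments 1 and 2, MCM2 read -0.69 and -0.11, and HMMR -0.80 and -0.29. CDC6 and CDC45 lay below the filter level in the AdFHIT pool of experiment 1, so their differences there are not given, and in experiment 2 they read -0.28 and -0.20. With values floored at the 40th percentile, their differences over both experiments were -0.68 and -0.55. The AdLACZ chips of experiment 1 had CDC45 at log2 levels of 5.71, below the filter, and 8.13. No member of either list passed the test, whether adjusted over all probe sets or adjusted over the list alone. All 30 genes of the mitotic list and 29 of the 31 genes of the replication list were lower in experiment 1, but only 17 and 20 were in experiment 2.

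The glycolysis and hypoxia list was higher with AdFHIT, with a median of 0.14 over 27 genes (camera adjusted p = 1.55e-08; adjusted p = 0.885 with an estimated correlation). Its median was 0.17 in experiment 1 and 0.09 in experiment 2, at percentiles 100 and 99.96 of 10000 random lists of matched level. Lists without a call reached high percentiles too, such as apoptosis at 99.03 in experiment 2. In experiment 1 23 of the 27 genes were higher, in experiment 2 20, and in both 16. Independent signs would share about as many, so the overlap does not show that the same genes replicated. The glycolytic enzymes TPI1 (0.31, SE 0.09) and ALDOC (0.32, SE 0.10) and the hypoxia-induced genes BNIP3L (0.37, SE 0.10) and NDRG1 (0.56, SE 0.16) had the smallest p-values, each at a limma adjusted p of 0.714. On 1 AdFHIT chip of experiment 1 TPI1 read a log2 level of 12.98, against 12.38 to 12.43 on the other 3 AdFHIT chips, and its difference was 0.46 in experiment 1 and 0.16 in experiment 2. The list's call was lost without the AdFHIT pool of experiment 1 or the AdLACZ pool of experiment 2, both with no block, which mixes in the difference between experiments.

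The p53 target list was higher by a median of 0.09 over 20 genes (camera adjusted p = 0.00886; adjusted p = 0.885 with an estimated correlation). Its median was 0.18 in experiment 1 and 0.08 in experiment 2. CDKN1A was its 1 member past the threshold when adjusted over the list alone (adjusted p = 0.0134, limma). With any 1 pool left out and no block its difference lay between 0.03 and 0.84, which mixes in its difference between experiments (0.77). The stress cytokine GDF15 (0.49, SE 0.17), PLK2 (0.43, SE 0.15) and GADD45A (0.30, SE 0.12) followed without passing it. In experiments 1 and 2, GDF15 read 0.93 and 0.05, PLK2 0.59 and 0.28, and GADD45A 0.43 and 0.17. The list's call was lost with no block (adjusted p = 0.333) and with hybridization 1 of every pool alone (0.111). It turned to lower without the AdFHIT pool of experiment 2 or the AdLACZ pool of experiment 1, both with no block. Those fits mix in the list's difference between experiments (median 0.60), so the turn does not show a reversed vector difference.

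Cytosolic ribosomal protein genes were lower, with a median of -0.03 over 44 genes (camera adjusted p = 0.00216; adjusted p = 0.885 with an estimated correlation), a direction that turned on the deposited values without quantile normalization (adjusted p = 0.0591, higher) and with scaling to the 75th percentile (adjusted p = 0.0144, higher). RPL24 (-0.20), RPL9 (-0.24), RPS9 (-0.12) and RPL34 had the smallest p-values in this list, and RPS9 read 0.03 with scaling to the 75th percentile. The list's median was -0.05 in experiment 1 and -0.02 in experiment 2, and RPL9 read -0.41 and -0.06. The list's call was also lost with hybridization 2 of every pool alone (adjusted p = 0.267). The same held with any 1 pool left out and no block, which mixes in the difference between experiments. The remaining 23 lists did not pass, with camera adjusted p between 0.184 and 0.993. For the growth factor list (median -0.03, mean 0.0020) and the metallothioneins (median 0.06, mean -0.0047) the median and mean differed in sign, and camera gave both as higher.

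Pathways tied to FHIT or to viral infection were among the lists without a call. The apoptosis list had a camera adjusted p of 0.559 over 19 genes, and its members with the smallest p-values were the caspase inhibitor CFLAR (0.32), the initiator caspase CASP9 (0.30) and BIRC5 (-0.33). CASP9 and BIRC5 differed in sign between the experiments: CASP9 read 0.64 in experiment 1 and -0.04 in experiment 2, and BIRC5 -0.91 and 0.25. Beta-catenin targets had an adjusted p of 0.661 over 13 genes, with ENC1 at -0.32, CTNNB1 itself at 0.20 and VEGFA at 0.21. AKT and PI3K signalling also had 0.661, over 17 genes, with RHEB at 0.24, GSK3B at 0.28 and MTOR at -0.23. In experiments 1 and 2, ENC1 read -0.49 and -0.16, VEGFA 0.41 and 0.01, RHEB 0.37 and 0.10, and GSK3B 0.45 and 0.11. The other 2 tested probe sets of CFLAR read -0.15 and -0.05, and those of VEGFA read -0.02 and -0.01. The other tested probe set read 0.13 for CASP9, -0.89 for BIRC5, 0.37 for RHEB, 0.30 for GSK3B and -0.04 for MTOR. Markers of other cells were mostly too dim to test: 2 fibroblast, 4 blood and 3 kidney or liver genes passed the filter, and the neurofilament gene NEFL had the smallest p of them (0.28, SE 0.09, limma adjusted p = 0.714). The interferon response list had a camera adjusted p of 0.358 over 26 genes, and the reference genes had 0.971 over 11 genes.

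**Figure D2:**
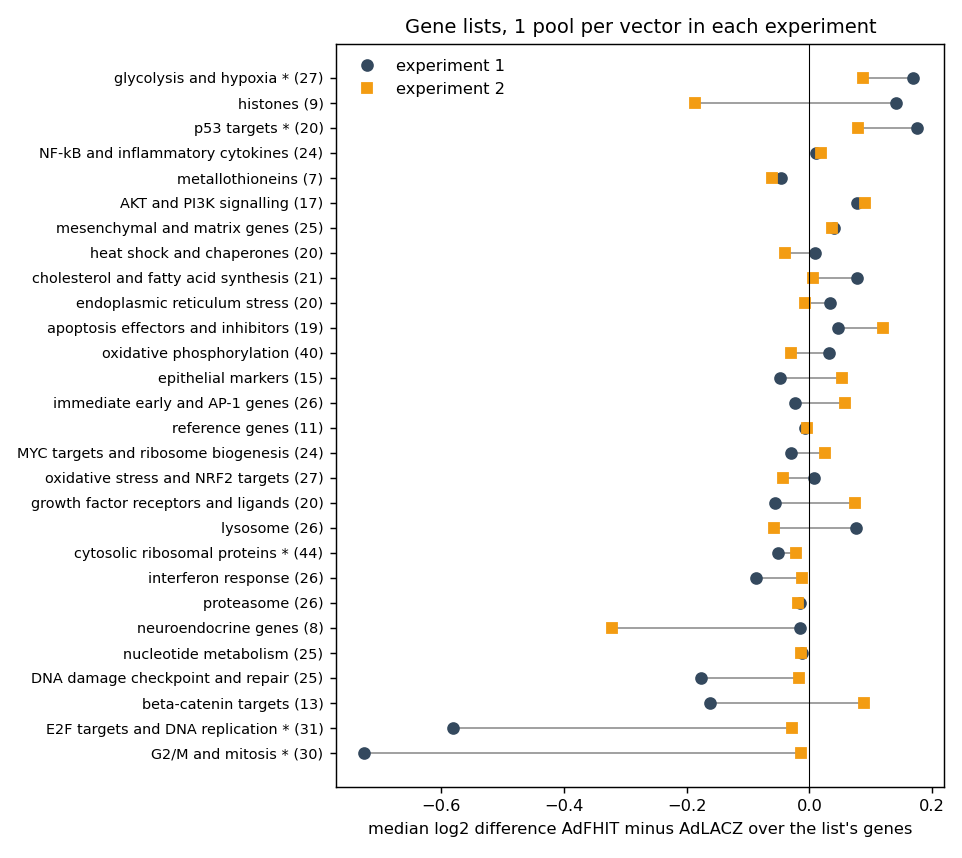
Median log2 difference (AdFHIT minus AdLACZ) over the genes of each tested list in experiment 1 (circles) and experiment 2 (squares), with the number of genes in brackets and an asterisk at the 5 lists past a camera adjusted p of 0.05. The G2/M and mitosis list lies at -0.73 in experiment 1 and at -0.01 in experiment 2, and the glycolysis and hypoxia list is above 0 in both.

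Set side by side, the experiments shared little of the measured difference between the vectors apart from FHIT. The mitotic list had a median log2 difference of -0.73 in experiment 1, below all random lists, and of -0.01 in experiment 2, at percentile 42.55 of random lists. The replication list read -0.58 and -0.03. Across the probe sets tested, the log2 differences of the 2 experiments had a Pearson correlation of 0.08 without FHIT and a Spearman correlation of 0.07, and 53.1% had the same sign. These are correlations across genes, which are not independent replicates. Even the 2 scans of the same chips gave vector differences that correlated at only 0.35 without FHIT. Measurement noise thus keeps such correlations low, and a low value does not show that true differences were unshared.

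At a fold of 1.5, 33 probe sets were higher in both experiments, where independent lists would share 9.96, and 25 were lower in both, where they would share 11.9. As many went opposite ways, 58 against 58, so the excess over independent lists at this fold does not by itself show that the experiments agree. At a fold of 2, 6 were higher in both, FHIT included, where 0.628 are expected, 7 were lower in both, where 0.552 are expected, and 3 went opposite ways. Across other settings the count at a fold of 1.5 ranged from 6 higher and 3 lower with a filter at the 60th percentile to 266 higher and 271 lower with no filter. The correlation turned to -0.08 with hybridization 1 of every pool alone. With 1 pool per vector in each experiment, none of these within-experiment values has a test.

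**Figure D3:**
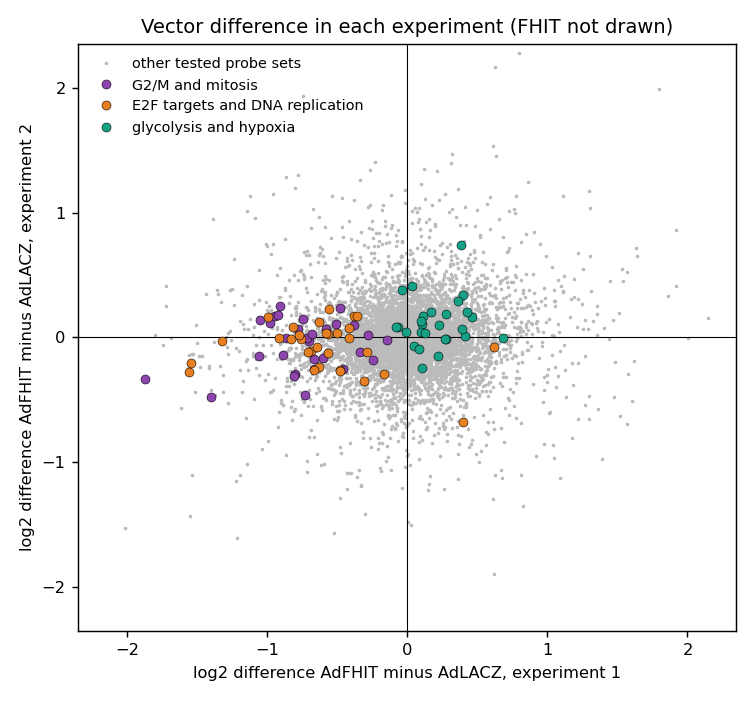
Log2 difference (AdFHIT minus AdLACZ) of each tested probe set in experiment 1 (x axis) and experiment 2 (y axis), without FHIT, with 3 gene lists coloured. Genes of the G2/M and mitosis list spread to the left of 0 on the x axis and around 0 on the y axis, and those of the glycolysis and hypoxia list lie mostly in the upper right.

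The difference between the vectors was then compared between the experiments on the 8 hybridizations. TOP2A read -1.87 in experiment 1 and -0.33 in experiment 2, and the RNA-binding protein gene TAF15 read -0.91 and 0.32. These were the 2 probe sets with a vector by experiment term past the threshold in limma, with adjusted p of 0.0270 for TOP2A and 0.0352 for TAF15. The mitotic and replication lists passed the same test (camera adjusted p = 1.19e-21 and 4.80e-13). Both still passed with an estimated correlation (camera adjusted p = 0.0417 and 0.0435), which was only 0.039 and 0.028 there. That estimate rests on hybridizations of the same RNA, so genes that vary together between cultures do not enter it. Nucleotide metabolism also passed at 0.0434 and not with an estimated correlation (adjusted p = 0.471). Its medians were -0.01 in both experiments. The spread in this test is that between hybridizations of the same RNA, so it measures technical error only. With 1 pool per vector and experiment, the term also holds any difference between cultures. On scan 1 alone 0 probe sets passed in limma, and on scan 2 alone or without a chip with low spike-in values 1 passed.

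**Figure D4:**
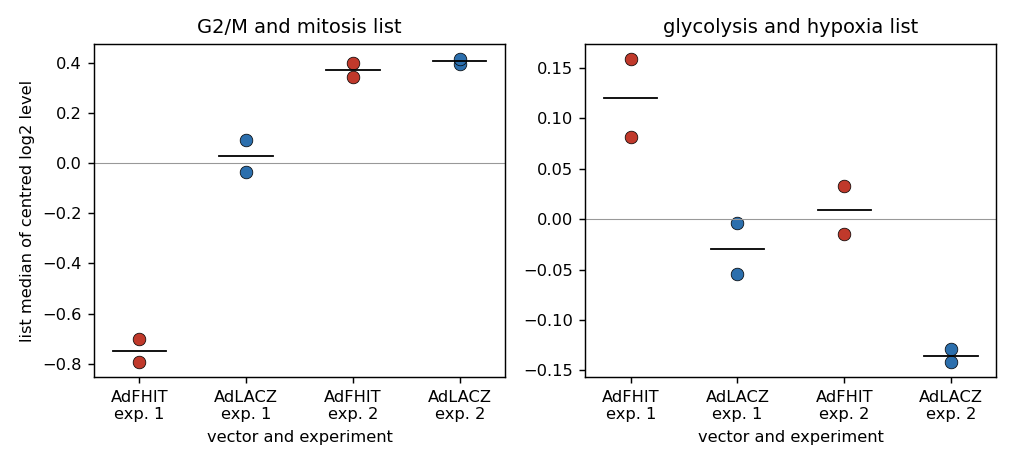
Median over a list's genes of the log2 level, each gene centred on its mean over the 8 chips, for each chip (points) with the mean of the 2 chips of a pool (bars). For the G2/M and mitosis list the AdFHIT chips of experiment 1 read -0.70 and -0.79, and all other chips lie between -0.04 and 0.41.

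The experiments themselves differed far more than the vectors. Chemokine and immediate early genes were much higher in experiment 2: CXCL8 by 4.06 (SE 0.14) and CXCL2 by 3.82 (SE 0.10) on the log2 scale. Others lay below the filter level in experiment 1, so they have a lower bound only: at least 12.6-fold for MAFF, 7.47-fold for DUSP2, 5.99-fold for CCN1 and 5.18-fold for CCL20. Enzymes of sterol synthesis were lower in experiment 2, with TM7SF2 at -2.78 and MSMO1 at -2.71. MVD was at least 6.48-fold lower, to a level below the filter. All these genes passed the test, with limma adjusted p between 7.90e-07 and 6.20e-05. In all, 1619 probe sets rose and 1565 fell from experiment 1 to experiment 2. Of the 28 lists 11 passed, and none of these calls holds with an estimated correlation (lowest adjusted p = 0.662). That estimate rests on 1 residual degree of freedom, so a miss does not show that a list is unchanged.

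Among these lists, 18 of 21 genes of cholesterol and fatty acid synthesis fell (median -1.19, camera adjusted p = 2.67e-09; adjusted p = 0.662 with an estimated correlation), INSIG1 (-2.49) and FDPS (-1.78) among them. In the lysosome list 19 of 26 fell and none rose (median -0.68, adjusted p = 4.60e-08, estimated correlation adjusted p = 0.662), for example NEU1 (-2.10) and CTSA (-1.93). Immediate early and AP-1 genes had 18 of 26 members that rose (median 1.08, adjusted p = 4.60e-08, estimated correlation adjusted p = 0.662), such as PHLDA1 (2.87) and DUSP1 (2.22). In the list of NF-kB and inflammatory cytokine genes, 16 of 24 rose (median 0.93, adjusted p = 8.31e-06, estimated correlation adjusted p = 0.662), including IL6 (2.75) and CXCL3 (2.78). The mitotic list had 20 of 30 genes that rose (median 0.83, adjusted p = 2.63e-06, estimated correlation adjusted p = 0.674), AURKB (1.30) and CDK1 (0.98) among them. Relative to all genes, this list rose by 0.58 with AdLACZ and by 1.21 with AdFHIT. It and the replication list passed the vector by experiment term, so their averages join unlike rises. Genes counted here passed a limma adjusted p of 0.05, as did 1619 risen and 1565 fallen of all 7535 probe sets. The replication, endoplasmic reticulum stress, nucleotide metabolism and p53 lists were also higher in experiment 2, and the oxidative phosphorylation and interferon lists lower (adjusted p from 1.51e-05 to 0.0216). With an estimated correlation these 6 had an adjusted p of 0.662 or 0.674. With 1 thaw behind each experiment the test rests on n = 2 pools each.

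The 2 scans of a chip, before and after the antibody step, correlated between 0.949 and 0.975 across probe sets. The brightest value of a scan lay between 55458 and 84775 before the step and between 30567 and 54984 after it, and the brightest 1% of probe sets read lower afterwards on every chip, by a median log2 difference between -0.24 and -0.14. For all probe sets but those of FHIT, the vector differences of the 2 scans correlated at 0.35 across genes, with a slope of 0.25. The median SD between the 2 hybridizations of a pool was 0.18 on the log2 scale before the step and 0.14 after it.

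The 3' minus 5' log2 difference of the ACTB control probe sets was 0.30 ± 0.09 with AdFHIT and 0.28 ± 0.09 with AdLACZ, and that of GAPDH was 0.04 ± 0.08 and 0.01 ± 0.05 (SD, n = 2). Within experiments 1 and 2, AdFHIT read higher by 0.01 and 0.02 for ACTB, by 0.01 and 0.05 for GAPDH, and by 0.18 and 0.56 for the mean of the bacterial spike-in probe sets. The spike-ins averaged a log2 level of 10.14 on hybridization 1 of AdLACZ in experiment 2 and between 10.81 and 11.33 on the other 7 chips. Without that chip, 2 probe sets passed the comparison of the vectors, both of FHIT, and the same number of gene lists, 5, passed.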

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

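The tests of the spike-in probe sets and of other splits of the pools were chosen after their results were seen, and the other explanations tested here were set down after the pattern but before the tested values.

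For cell cycle genes, the vector differences of the RNA pools differed between the experiments by more than the spread between hybridizations. The vector by experiment term, fitted with limma on the 8 hybridizations, gave TOP2A a log2 difference of 1.54 (SE 0.18, adjusted p = 0.0270) and TAF15 one of 1.24 (SE 0.16, adjusted p = 0.0352). In camera the same term gave an adjusted p of 1.19e-21 for the G2/M and mitosis list and 4.80e-13 for the E2F list. With a correlation estimated between hybridizations of the same RNA, these were 0.0417 and 0.0435. For nucleotide metabolism the term gave 0.0434 (0.471 with an estimated correlation). With 1 pool per vector and experiment, these tests do not separate the vector from differences between cultures.

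The mitotic list in experiment 1 has a median log2 difference of -0.73 over 30 genes, all lower with AdFHIT. A single deviating chip is argued against, since the 4 chip-by-chip comparisons of experiment 1 gave medians from -0.75 to -0.68. Normalization or the choice of scan is argued against as well, with medians from -0.72 to -0.67 on either scan alone, on the deposited values and with scaling to the 75th percentile. Slower growth of the control cells in experiment 2 would need a lower list there, but AdLACZ read higher in experiment 2 than in experiment 1 by 0.58 relative to all genes, and AdFHIT by 1.21. An effect of FHIT that differs between thaws may be an explanation, and so may a difference between the 2 cultures of experiment 1, since 1 RNA pool per vector leaves vector and pool confounded there.

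Of 128 sets of 4 chips tested for a chip far from the others, 5 had one. The nominal rate of the rule would give about 6.4 for independent chips. Each set holds 2 hybridizations from each of 2 experiments, so the counts cannot show whether deviating chips are in excess. Hybridization 1 of AdLACZ in experiment 2 read 10.14 for the mean log2 level of the bacterial spike-ins (others 10.87 to 10.98) and 7.81 for BioB-M (others 9.45 to 9.66). All 9 spike-in probe sets were lowest there among the 8 chips, which is consistent with less spike-in material on that chip, and no biological explanation was tested. Hybridization 2 of the same pool read 13.36 for BioDn-3 (others 12.86 to 12.88). In experiment 1, SAT1 read 12.52 on hybridization 2 of AdLACZ (others 12.33 to 12.36), and TPI1 read 12.98 on hybridization 2 of AdFHIT (others 12.38 to 12.43).

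With no experiment block, 2 probe sets passed between the vectors. Of the 3 splits of the 4 pools into equal groups, 2 gave as many, and the highest of the others, the split by experiment, gave 3006. That count points to a structure of the samples by experiment, and 3 splits cannot give a share under 0.05. With the experiment as a block the count between the vectors is 3.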

How the results depend on the processing

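Chosen after the data were seen were leaving out the chip with low spike-in values, the estimated correlation on hybridizations, and all alternatives for the correlation of experiments, the vector by experiment term, the scan slope and the ACTB difference. So were single hybridizations, floor and pseudocount for the counts shared by experiments, and normalization for the comparison of experiments. FHIT kept its direction and call in all 21 settings of the fit, with log2 differences from 8.77 to 10.39 and from 7.99 to 8.59 where all pools were kept. Few arrays and dim probe sets near background limit the rest. The cause of the changes below was not tested, except that fewer chips add noise, filters change the probe sets tested, and leaving out a pool without the block adds the difference between experiments to that between vectors. The lone pool is then assumed to vary like the other vector's. Camera was run with its variance trend throughout and with no random block, so its counts of 5 lists beside the random block and the eBayes options repeat those without them.

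The count of 3 probe sets became 21 with a random pool block and 15 with hybridization 1 only. With no replicate block (no pairing) it was 2. Probe sets higher and lower by 1.5-fold in both experiments numbered 102 and 91 on scan 1, 79 and 74 with hybridization 2 only, 61 and 63 with hybridization 1 only, 266 and 271 with no filter, 6 and 3 with the 60th percentile filter, 15 and 5 with the floor, 13 and 11 with a pseudocount of 32, 57 and 42 without the chip with low spike-ins, and 6 and 7 at a fold of 2. The correlation of the experiments was 0.034 on scan 1, 0.102 on scan 2, -0.082 with hybridization 1 only, 0.027 with no filter and 0.123 with the 60th percentile filter. The vector by experiment count was 0 on scan 1, 1 on scan 2 and 1 without that chip, against 2 as reported (559 at an unadjusted p under 0.05). The scan slope was 0.280 on deposited values and with scaling to the 75th percentile, where the median difference of all genes between experiments was -0.107.

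Of the 5 lists, 0 passed with an estimated correlation, with fry or with an estimated correlation on hybridizations. The adjusted p-values in that order were 0.885, 0.678 and 0.154 for p53 targets, 0.885, 0.678 and 0.297 for E2F targets, 0.885, 0.714 and 0.297 for G2/M, 0.885, 0.678 and 0.154 for ribosomal proteins, and 0.885, 0.630 and 0.145 for glycolysis. The p53 list had 0.333 with no block and 0.111 with hybridization 1 only. The ribosomal list had 0.267 with hybridization 2 only, and turned to higher on deposited values (0.0591) and with scaling to the 75th percentile (0.0144). Without each pool in turn, 8 to 11 lists passed. The range was 3.90e-05 to 0.509 for p53 targets, 1.19e-17 to 0.452 for E2F targets, 2.76e-23 to 0.105 for G2/M, 0.0649 to 0.329 for ribosomal proteins and 0.00413 to 0.199 for glycolysis.

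Of the named genes' values over alternatives, 940 were labelled as the same, 12 moved past the threshold and 34 were labelled as turned in sign. The 940 include the values of each experiment alone, labelled by a size rule that any such value meets. Among these, CASP9 (-0.04) and BIRC5 (0.25) had the opposite sign in experiment 2. BIRC5 read 0.061 with hybridization 1 only and RPS9 0.028 with scaling to the 75th percentile. With hybridization 1 only and hybridization 2 only, log2 differences were 0.06 and 0.58 for CFLAR, 0.09 and 0.31 for CTNNB1, 0.44 and 0.12 for GSK3B, 0.11 and 0.52 for TPI1, and 0.18 and 0.56 for BNIP3L. In the same order, CENPF read -0.83 and -0.37, and HMMR -0.34 and -0.76. CDC45 (-0.03 and -1.72) and ROM1 (1.86 and 0.61) moved further, with a pool below the filter level, so their sizes are not exact. SNCG read 0.88 on scan 1 and 0.25 on scan 2. Without each pool, the log2 differences that turned sign ranged from -0.97 to 2.49 for NR4A1, -1.87 to 0.39 for CXCL5, -1.67 to 0.58 for XPOT, -0.58 to 1.57 for GDF15, -0.45 to 1.31 for PLK2, -0.81 to 1.41 for GADD45A, -0.32 to 0.96 for CFLAR, -0.72 to 1.32 for CASP9, -0.99 to 0.33 for BIRC5, -0.0050 to 0.41 for CTNNB1 and -0.0037 to 0.43 for VEGFA. They ranged from -0.14 to 0.61 for RHEB, -0.82 to 0.016 for MCM2, -0.78 to 0.041 for CHAF1A, -1.14 to 0.044 for HMMR, -0.56 to 0.084 for RPL9, -0.30 to 1.04 for BNIP3L and -0.40 to 1.04 for ALDOC. CDC6 (-1.84 to 0.0046) and CDC45 (-2.80 to 1.05) did so with a pool below the filter level, so their sizes are not exact. All other named genes kept their sign. Their ranges included 0.03 to 0.84 for CDKN1A, -2.20 to -0.0054 for TOP2A, -1.78 to -0.10 for KIF11, -0.83 to -0.14 for BCAP31 and 0.13 to 0.48 for WNT6. Others were 0.29 to 1.08 for NINJ1, 0.20 to 0.77 for RHOQ, 0.13 to 1.001 for SNCG, -0.91 to -0.27 for CBX3 and -1.15 to -0.24 for ATP9A. SPOCK1 ranged from -0.73 to -0.18, RPL34 from -0.79 to -0.13, MTOR from -0.42 to -0.04 and NDRG1 from 0.26 to 0.86. NRTN ranged from 0.66 to 1.34 and POLE3 from -0.93 to -0.33. ROM1 (0.60 to 1.87) and SLC6A11 (0.49 to 1.47) had a pool below the filter level, so their sizes are not exact.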

Other observations

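Every gene in this part was picked after its values were seen.

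Fitting the 8 hybridizations with the RNA pool as a random block called BCAP31 (log2 difference -0.48, limma adjusted p = 0.00142), the lysosomal lipase LIPA (-0.41), the phosphodiesterase PDE4B (-0.39) and CDKN1A (0.43, adjusted p = 0.0148). It also called 1 probe set each of ODC1 (-0.37, adjusted p = 0.0406), SAT1 (-0.33, adjusted p = 0.0228) and the microtubule protein gene MAPT (0.87). The other tested probe set read -0.14 for ODC1, -0.05 for SAT1 and -0.27 for MAPT. The consensus correlation of that fit was -0.27, with only 1 residual degree of freedom between pools, so it does not show a smaller spread between pools. The adjusted p-values of that fit rest on this negative correlation. With the 8 hybridizations taken as independent, 4 probe sets passed. The vector by experiment term had 559 probe sets at an unadjusted limma p under 0.05, where 376.75 are expected by chance. Of the fit's 21 calls, only the 2 FHIT probe sets and the unnamed one also passed on the 4 pool means.

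Probe sets with a measured difference of 2-fold or more the same way in both experiments were mostly dim. Apart from FHIT and ROM1 they include the serotonin receptor gene HTR4, at 1.11 and 1.13 on the log2 scale in experiments 1 and 2. With 1 vector below the filter level and so only a lower bound, the phosphatase subunit gene PPP2R3A was at least 2.08-fold higher with AdFHIT. The retinal transcription factor gene CRX was at least 1.83-fold lower. None of these 3 passed the limma test on the pool means (adjusted p from 0.203 to 0.685). PPP2R3A and CRX were among the calls of the random block fit above (limma adjusted p = 0.0432 and 0.0158).

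The neuroendocrine list of 8 genes had a median log2 difference of -0.01 in experiment 1 and of -0.32 in experiment 2, at percentiles 44.41 and 0.17 of random lists. Its camera adjusted p over both experiments was 0.661, and that of the vector by experiment term was 0.604.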
